A study of Homo sapiens with 12 samples.

How the data were processed

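RNA of HEK293T cells from 4 groups of 3 samples was measured on one-colour Agilent gene expression arrays, 1 array per sample. The groups were cells given an siRNA against Ataxin-2, cells given a control siRNA, cells given a plasmid for Halo-tagged Ataxin-2 and cells given a plasmid for the Halo tag alone, and RNA was taken 48 h after transfection. Per the labels' protocols the RNA was treated with DNase on the column and labelled with Cy3.

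The deposited scanner files hold, per the file headers, signal intensity from Feature Extraction 10.10.1.1 with protocol GE1_1010_Sep10, and the processed signal is an intensity from which the software had subtracted background, with trends across the array removed. The headers give probe coordinates in hg19. The deposited series matrix holds log2 values of the authors whose making is not described in the sources used here. Over the 20427 probes with values on all arrays, each of its columns followed log2 processed signal with a slope of 1, lay 0.45 to 0.58 above the values computed here, and was not centred by probe. Column medians were 0.07, -0.13 and -0.08 for knockdown, -0.23, -0.06 and -0.02 for control siRNA, 0.14, 0.28 and 0.30 for Halo-Ataxin-2 and 0.16, 0.39 and 0.44 for Halo alone, over the probes that have a value.

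Each array had 58717 spots other than controls, of which 47.8% to 56.0% were well above background, and 1 spot was saturated over all arrays. Control spots and spots marked as outliers were left out. The log2 processed signal was reduced by each array's 75th percentile, and the spots of a probe were averaged. Probes were kept when well above background on all 3 arrays of at least 1 group (25388 of 50599). Of the 50599 probes, 28174 were named through their accession, 2618 through a current symbol and 620 through an older symbol, and 19187 kept the name in the file. Among kept probes the one with the highest mean over all arrays stood for a gene, which mattered for 4694 genes with several. This gave 18992 genes or names, 14877 of them recognised genes. A gene not well above background on any array of a group has only a bound there. A group with at least 1 array well above background was counted as measured, or as well above background. Values counted so can still lie near the floor. Its fold is given as "at least", from the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal well above background and the probe's own. No fold is given where that is under 1 or both groups were dim.

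Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes), 1 fit of 4 group means to all 12 arrays with 8 residual degrees of freedom, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Contrasts were knockdown minus control siRNA, Halo-Ataxin-2 minus Halo alone, and the difference of both. Of 33 gene lists fixed before the data were examined 32 were tested with camera at a preset correlation of 0.01, with adjustment over 64 tests, and with an estimated correlation and fry beside it. Of the mitochondrial-encoded list no member was measured. A test of genes with the heptamer UAUUUAU in the 3 prime UTR was not run, since it needs a genome, which was not used here. Overlaps used Fisher's exact test. Other steps used Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures matplotlib 3.10.9.

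Genes were named by a rule fixed before the data were examined. It took ATXN2 and ATXN2L, the 12 largest rises and falls per comparison by fitted change among called, recognised genes whose arrays did not overlap, and up to 4 members of each described list with the smallest adjusted p, of which some are printed. It also took the 5 genes per direction called in both comparisons with the largest smaller change, and the 5 with the smallest adjusted p for the difference.

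The arrays lay on 3 slides. Slide 1 held knockdown 1, control siRNA 1, Halo-Ataxin-2 2 and Halo alone 2, slide 2 held both remaining arrays of each siRNA group with Halo-Ataxin-2 3 and Halo alone 3, and slide 3 held Halo-Ataxin-2 1 and Halo alone 1. In the overexpression experiment the deviations of same-numbered arrays from their group means correlated at 0.38, 0.36 and 0.29, so that the numbers, which follow the slides, pair those arrays. Replicates of a group correlated at 0.990 or higher across genes.

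The steps were tested on simulated data made from 18981 genes. Of genes changed by 1 on the log2 scale 71.6% were recovered in the knockdown comparison and 74.0% in the overexpression comparison, and of those changed by 0.5, 52.7% and 42.7%. There were 10 false calls among 136 and 4 among 122. The simulated noise was independent between genes and between arrays, without slide or pair effects, so these rates do not cover such dependence. Alternatives covered background correction (normexp with offset 50), quantile and median scaling, the series matrix values, the filter on dim probes, outlier spots, the choice of probe, the variance model, the arrays in the fit, the replicate number and the slide as blocks, leaving out each array, and a threshold of 0.01.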

Results

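Genome-wide mRNA levels were measured in HEK293T cells, an established human embryonic kidney line, 48 h after the level of Ataxin-2 was altered. Ataxin-2, encoded by ATXN2, is an RNA-binding protein that works with poly(A)-binding protein. In one experiment cells received 10 nM of an siRNA against Ataxin-2 or a control siRNA, and in the other 8 µg of a plasmid coding for Ataxin-2 fused to the Halo tag or for the Halo tag alone. Each of the 4 groups held 3 samples, and each sample was hybridised to its own one-colour array. No label says that the samples came from separate cultures, so p-values measure the spread between these samples, which may be technical. Between 47.8% and 56.0% of the spots on an array were well above background, and the number of arrays limits the precision of every value. Levels are given as log2 processed signal relative to the array's 75th percentile.

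The targeted mRNA was examined first. On the arrays labelled Ataxin-2 knockdown, ATXN2 stood at 0.38, 0.19 and 0.07 on the log2 scale, against 3.43, 3.53 and 3.44 with the control siRNA. This was a fall by 3.25 ± 0.10 (SE, n = 3 per group) or 9.53-fold, with a limma adjusted p of 4.8e-08. Every SE given here comes from the fit to all 12 arrays, with 1 spread per gene shared by both experiments. The median SD over genes was 0.15 with Halo-Ataxin-2 and 0.14 with Halo alone. It was 0.10 after knockdown and 0.09 with control siRNA, a difference that the shared SE and its p-values do not show. The probe lies on chromosome 12 from 111890330 to 111890389 in hg19, and no exon or UTR is named for it in the files. A second, far dimmer ATXN2 probe read -0.24. ATXN2L, the paralogue of ATXN2, differed by 0.03 ± 0.12 between the same groups (adjusted p = 0.87). In the overexpression experiment the ATXN2 probe read 2.46, 2.66 and 2.48 with Halo-Ataxin-2 and 2.66, 2.77 and 2.89 with Halo alone, a difference of -0.24 ± 0.10 that did not pass the test (adjusted p = 0.11). A construct that carries only the coding part of the mRNA would be missed by a probe outside that part, and the position of the probe in the mRNA is not stated in the files, so this probe does not check the overexpression. With the mean of both ATXN2 probes the difference passed the test (-0.36, adjusted p = 0.0133; over all alternatives the adjusted p ran from 0.0133 to 0.285). ATXN2L differed there by -0.07 ± 0.12 (adjusted p = 0.71).

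**Figure D1:**
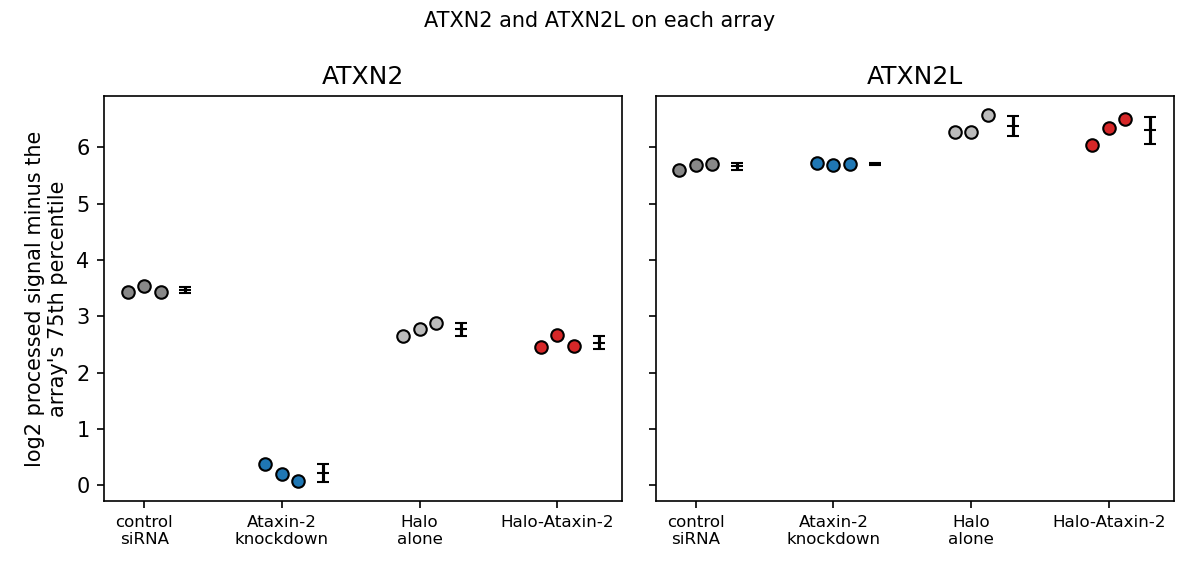
Log2 level of ATXN2 and ATXN2L (processed signal minus the array's 75th percentile) on each of the 12 arrays; points are arrays, bars beside them the mean ± SD of 3. ATXN2 lies between 0.07 and 0.38 on the knockdown arrays and between 3.43 and 3.53 with control siRNA, while both overexpression groups lie between 2.46 and 2.89.

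The first comparison asked which mRNAs change when Ataxin-2 is depleted. The clearest group was the amino acid stress response, the set of genes driven by the transcription factor ATF4: 36 of its 40 measured members fell, none rose, and 4 did not pass the test. Among the members, CHAC1, which degrades glutathione, fell by 3.69 ± 0.15, SLC7A11, the cystine transporter, by 3.39 ± 0.11, DDIT4, an inhibitor of mTOR signalling, by 3.33 ± 0.07, NUPR1 by 3.23 ± 0.09 and CTH, the enzyme that makes cysteine from cystathionine, by 1.80 ± 0.07 (log2 change ± SE, n = 3 per group; adjusted p from 4.2e-09 to 3.2e-07). Adjusted over the list alone, 36 fell and 1 rose. The median change of the list was -0.99, and it was -0.98 within each of the 2 slides that held arrays of this experiment. Its median level was 2.22 after knockdown and 3.29 with control siRNA. In the other experiment it was 2.23 with Halo-Ataxin-2 and 2.32 with Halo alone. In a principal component analysis the first component, with 77.8% of the variance, parted the siRNA arrays from the plasmid arrays. Levels of the list therefore do not compare across the experiments. Untreated cells were not measured, so a fall after knockdown cannot be told from a rise with the control siRNA. The camera test gave an adjusted p of 8.98e-29 against all other genes, 0.00166 with an estimated correlation and 5.20e-23 with the slide as a block. Outside this list, CCND1, which encodes cyclin D1, fell by 2.02 ± 0.11, and the glycine transporter gene SLC6A9 fell by 2.56 ± 0.06, whereas TXNIP, an inhibitor of thioredoxin, rose by 1.16 ± 0.06.

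**Figure D2:**
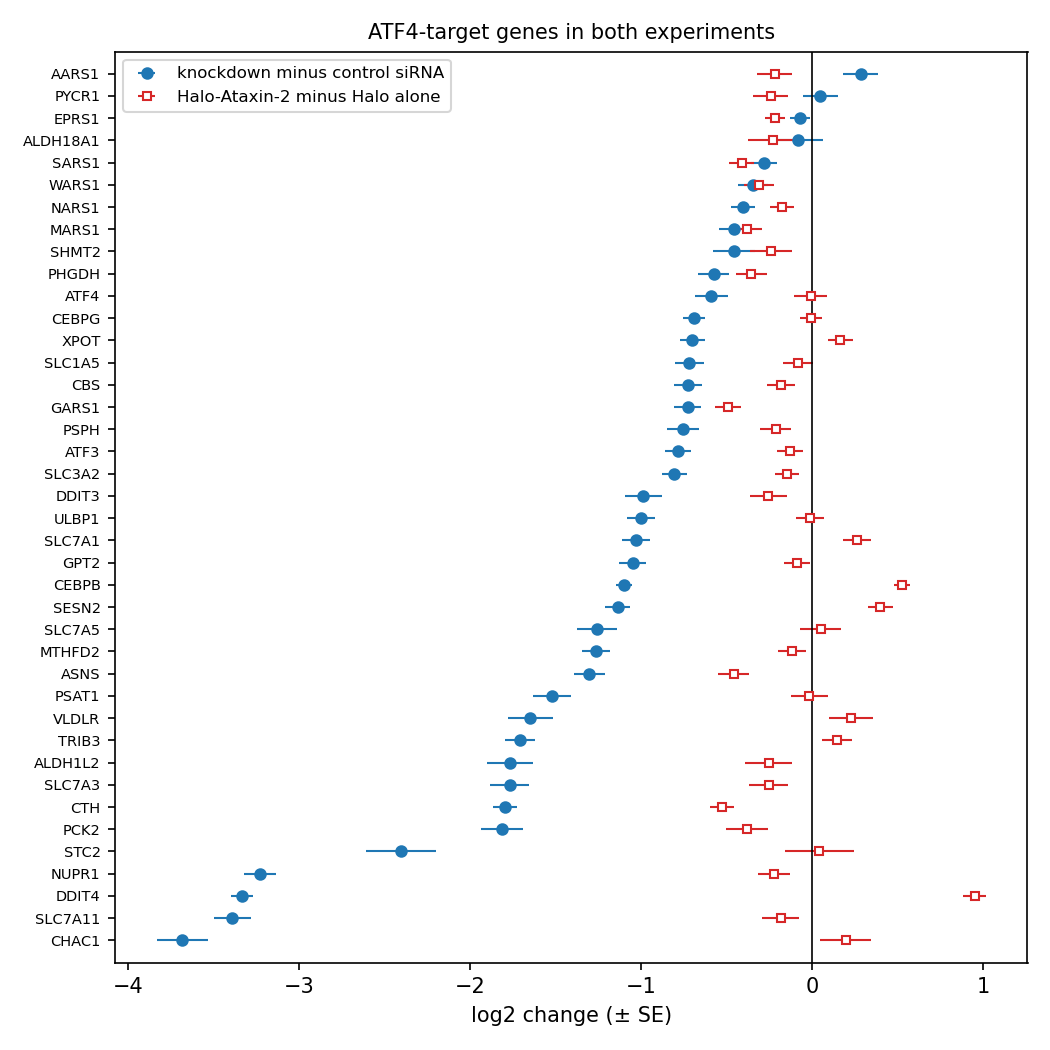
Log2 change ± SE of each of the 40 measured ATF4-target genes after knockdown (filled circles) and with Halo-Ataxin-2 (open squares), 3 arrays per group. The median is -0.99 after knockdown and -0.18 with overexpression.

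Outside that list, FUT1, a fucosyltransferase, fell 11.4-fold after knockdown and S100P, a calcium-binding protein, at least 12.6-fold, since it was not well above background on any knockdown array. CSTA, SLC4A8, MSH4, ARHGAP9 and the antisense transcript VLDLR-AS1 were also taken by the naming rule, which goes by fitted values. None was well above background after knockdown, so they have no rank, only bounds of at least 2.53-fold, 2.52-fold, 2.51-fold, 3.12-fold and 4.89-fold. The call of SLC4A8 was lost without the filter on dim probes (log2 change -0.96, adjusted p = 0.442), where another probe stood for it; over all its alternatives the adjusted p ran from 1.19e-07 to 0.442. The largest rises of recognised genes counted as measured on both sides were those of the potassium channel gene KCNC1 (2.43 ± 0.08), SPATA18 (2.11 ± 0.15), SCGB1D2 (2.07 ± 0.37), the neurofilament gene NEFM (2.05 ± 0.09), SCGB1D1 (2.01 ± 0.26), the noncoding KCNQ1OT1 (1.88 ± 0.22), the myogenic factor gene MYOD1 (1.88 ± 0.10), PTPRD (1.79 ± 0.38), CNRIP1 (1.74 ± 0.07) and the smooth muscle actin gene ACTA2 (1.72 ± 0.06). The mean levels of PTPRD, SCGB1D1 and SCGB1D2 over all arrays were -5.07, -4.29 and -4.25. Genes given only bounds lay as low (ARHGAP9 -4.90, VLDLR-AS1 -3.64), so the sizes of these rises are uncertain. INPP5D rose at least 3.21-fold and SMAD5-AS1 at least 3.48-fold from a level not well above background. Adjusted p lay at or below 0.0054 for all of these.

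Of 10 measured markers of epithelial carcinoma lines, 4 fell and none rose, namely S100P, the cadherin gene CDH1 (at least 5.00-fold), EPCAM (-0.70 ± 0.07) and the splicing factor gene ESRP2 (-0.66 ± 0.05). Adjusted over the list alone 4 fell as well. The list passed the camera test (adjusted p = 0.00733) but not with an estimated correlation (adjusted p = 0.126) or with the series matrix values (median -0.06, adjusted p = 0.161), and its median was -0.15 and -0.27 within the slides. That median was -0.09 with normexp and -0.06 without the filter on dim probes, and -0.08 and -0.38 without knockdown replicates 2 and 3. Nuclear-encoded subunits of oxidative phosphorylation moved the other way, with 29 of 64 members raised and none lowered (31 and none adjusted over the list alone), among them UQCRC1 (0.94 ± 0.13) and NDUFA5 (0.78 ± 0.07). Their median change was 0.21, or 0.25 and 0.21 within the slides, with adjusted p = 1.83e-06 from camera and adjusted p = 0.440 with an estimated correlation. Of 31 proteasome subunits 11 rose and none fell (12 and none adjusted over the list alone; adjusted p = 0.00128, and adjusted p = 0.392 with an estimated correlation), with a median of 0.15 overall and 0.17 and 0.16 within slides. PSMC2 rose by 0.36 ± 0.05, while its next brightest probe read 0.08. Of 25 heat shock proteins on a list labelled cytosolic 11 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.0226, and adjusted p = 0.138 with an estimated correlation). The risers included HSPA1A (0.82 ± 0.10) and HSPE1 (0.89 ± 0.05), whose protein is mitochondrial despite the label. The median of the list was 0.22, and 0.21 within each slide. With quantile normalization neither the proteasome list (median 0.07, adjusted p = 0.139) nor the heat shock list (median 0.12, adjusted p = 0.0929) was called. After removal of GC and level trends, chosen after seeing the data, the proteasome, heat shock and decay lists were not called (medians 0.06, 0.11 and 0.09, adjusted p = 0.121, 0.0577 and 0.138). Of 53 factors of mRNA deadenylation, decapping and decay 19 rose and 4 fell (21 and 4 adjusted over the list alone), BTG2 by 0.98 ± 0.07 and EXOSC7 by 0.87 ± 0.08. That list passed at a median of 0.15 (adjusted p = 0.0292) but not with an estimated correlation (adjusted p = 0.198) or with the slide as a block (adjusted p = 0.0541), and its medians within slides were 0.15 and 0.14. Nor was it called with quantile normalization (median 0.10, adjusted p = 0.119), normexp (adjusted p = 0.0663) or the series matrix values (adjusted p = 0.0908). The other lists called here kept adjusted p at or below 0.0382 with the slide as a block.

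In all, 5486 of 18992 genes changed after knockdown by limma at an adjusted p under 0.05, with 3111 higher and 2375 lower. With quantile normalization it was 2476 higher and 2540 lower, so the excess of rises depended on the normalization. Fitted changes of at least 2-fold leaned to loss, with 182 rises and 354 falls. These counts include genes with a group not well above background, whose fitted values measure no size, so the lean may not hold for measurable genes. With the slide as a block 7903 genes were called (4631 higher, 3272 lower), and over all genes the changes within both slides correlated at r = 0.743. Without the arrays of slide 1 the count was 3392, an alternative chosen after seeing the data.

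The second comparison asked which mRNAs change when Ataxin-2 is supplied in excess. Of 43 measured mRNAs known for AU-rich elements, sequences in the 3 prime UTR that govern mRNA decay, 15 rose and none fell (20 and none adjusted over the list alone), including the cell cycle genes CDKN1B (1.12 ± 0.11) and CCND1 (1.09 ± 0.11), IER3 (0.78 ± 0.08) and NFKBIA, an inhibitor of NF-kB (0.72 ± 0.06). Their median change was 0.30, and 0.29, 0.27 and 0.23 within the 3 slides; camera gave an adjusted p of 6.90e-09, and 0.00223 with an estimated correlation. Of 27 immediate-early and growth factor response genes 11 rose and none fell, also when adjusted over the list alone, with the nuclear receptor gene NR4A3 at 1.16 ± 0.10, the feedback inhibitor gene SPRY2 at 0.94 ± 0.10 and IER5 at 0.72 ± 0.07. This list had a median of 0.28, or 0.38, 0.27 and 0.34 within slides, with adjusted p = 1.45e-06, and 0.00756 with an estimated correlation. Of 15 NF-kB and inflammatory targets 6 rose and 1 fell (9 and 1 adjusted over the list alone), CD83 by 0.87 ± 0.08. The NF-kB list passed the preset test (adjusted p = 4.45e-05) and not that with an estimated correlation (adjusted p = 0.103). Its median was 0.41, and within slides 0.48, 0.34 and 0.35, but 0.15 with normexp. The normexp medians of the AU-rich and immediate-early lists were 0.21 and 0.16, and all 3 lists stayed called there. NFKBIA and IER3 belong to more than one of these lists.

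Of 64 oxidative phosphorylation subunits 43 fell and none rose (53 and none adjusted over the list alone), NDUFA8 by 0.41 ± 0.07 and COX6C by 0.40 ± 0.07; the median was -0.32, or -0.31, -0.30 and -0.33 within slides (adjusted p = 5.26e-13, and adjusted p = 0.267 with an estimated correlation). Of 31 proteasome subunits 22 fell and none rose (25 and none adjusted over the list alone), PSMC3 by 0.41 ± 0.07 and PSMD1 by 0.40 ± 0.05, with a median of -0.25, or -0.28, -0.26 and -0.26 within slides (adjusted p = 9.83e-08, and adjusted p = 0.198 with an estimated correlation). Of 79 cytoplasmic ribosomal proteins 17 fell and none rose (30 and none adjusted over the list alone), RPL30 by 0.34 ± 0.08 and RPS27A by 0.27 ± 0.06, at a median of -0.24, or -0.20, -0.23 and -0.32 within slides (adjusted p = 2.00e-08, and adjusted p = 0.546 with an estimated correlation). Of 43 translation factors 14 fell and 1 rose (21 and 1 adjusted over the list alone), EIF2B2 by 0.47 ± 0.06 and EIF3M by 0.30 ± 0.06, at a median of -0.22, or -0.17, -0.16 and -0.25 within slides (adjusted p = 0.000183, and adjusted p = 0.321 with an estimated correlation). The median over all genes was itself -0.10 in this comparison. With quantile normalization the ribosomal and translation factor lists were not called (medians -0.02 and -0.05, adjusted p = 0.394 and 0.231), nor were COX6C, NDUFA8, RPL30, RPS27A and EIF3M as single genes, and the medians of the oxidative phosphorylation and proteasome lists were -0.12 and -0.09. After removal of GC and level trends, chosen after seeing the data, the ribosomal median turned to 0.00 (0.00378, adjusted p = 0.898) and the translation factor list was not called (median -0.03, adjusted p = 0.367), while the other 2 medians were -0.14 and -0.09. RPL30 also lost its call without Halo alone replicate 2 or 3 (adjusted p up to 0.0502 for these). With the slide as a block, each of the 7 lists called on overexpression had an adjusted p at or below 0.000413.

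**Figure D3:**
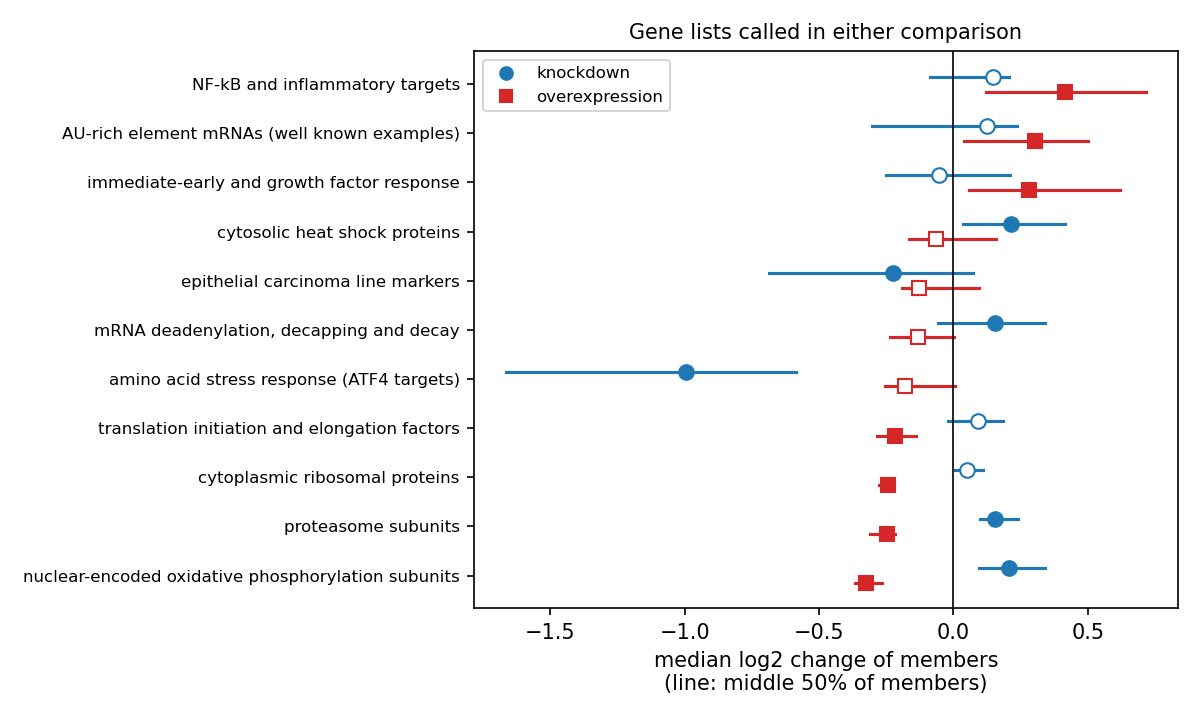
Median log2 change of the measured members of each list called in either comparison, for knockdown (circles) and overexpression (squares), with lines over the middle part of the members (between the quartiles); filled symbols mark camera adjusted p under 0.05 and open symbols the rest. Oxidative phosphorylation subunits sit at 0.21 after knockdown and -0.32 with overexpression.

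The largest changes with Halo-Ataxin-2 among genes counted as well above background in both groups were those of 1 probe for SOX13 (3.62 ± 0.15, 12.3-fold) and 1 for AGO1 (2.91 ± 0.15, 7.50-fold), with adjusted p of 2.1e-06 and 5.7e-06. The next brightest probes for SOX13 and AGO1 read 0.15 and -0.10, and both probes that rose carry runs of CAG triplets. The same held for TFEB, a regulator of lysosomal genes, at 1.83 ± 0.07 on a probe with such a run and -0.19 on another. Further rises were those of GDF10, a growth factor gene (2.01 ± 0.19), and PAQR9 (1.91 ± 0.14). OXGR1 (at least 2.82-fold), TIGD3 (at least 2.70-fold), the cytochrome P450 gene CYP2U1 (at least 2.00-fold), the sphingosine phosphate receptor gene S1PR1 (at least 1.89-fold), the iron exporter gene SLC40A1 (at least 1.42-fold), SSR4P1 (at least 1.32-fold), ZNF365 (at least 1.31-fold) and ZNF319 (at least 1.06-fold) were not well above background with Halo alone. OXGR1 lost its call with the replicate block (adjusted p = 0.0556) and without Halo alone replicate 2 (adjusted p = 0.0772), and over all its alternatives the adjusted p ran from 0.0132 to 0.100. BTG2, TOB1 and TOB2, which recruit the deadenylase that shortens poly(A) tails, rose by 0.95 ± 0.07, 1.01 ± 0.08 and 1.03 ± 0.09. The list of deadenylation and decay factors that they belong to was not called, with 6 of 53 higher and 12 lower (median -0.13, adjusted p = 0.298).

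The 12 falls with Halo-Ataxin-2 taken by the naming rule were largely of dim genes, whose fitted values give no rank. KRTAP19-7 was at least 4.30-fold and LINC01940 at least 2.40-fold lower. MSANTD1 fell by 1.75 ± 0.27, DNAAF4, an assembly factor of ciliary dynein, by 1.58 ± 0.31, LRRC39 by 1.28 ± 0.26 and NECTIN3-AS1 by 1.37 ± 0.42. DNAH6, IFT57, ANKAR, HMCN1, ANO2 and SUGT1P4-STRA6LP also passed the test, with no fold given since a group, or both, was not well above background and no bound above 1 followed. NECTIN3-AS1 lost its call with the replicate block (adjusted p = 0.0583, range over alternatives 0.0106 to 0.115). NECTIN3-AS1 and SUGT1P4-STRA6LP (range 0.000801 to 0.137) lost theirs in most fits without single arrays of either experiment, ANO2 (range 0.00322 to 0.122) without Halo-Ataxin-2 replicates 2 or 3 or Halo alone replicate 1, and HMCN1 (range 0.00134 to 0.151) without Halo alone replicate 2. With normexp neither these 4 nor ANKAR, OXGR1, ZNF319 and ZNF365 were called with overexpression (adjusted p from 0.0627 to 0.383).

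In all, 3771 of 18992 genes changed with Halo-Ataxin-2, 1706 higher and 2065 lower. The fitted changes of at least 2-fold were 181 rises and 34 falls, again including genes with a group not well above background. The share of rises among the calls, 45.2%, became 66.8% with quantile normalization (2060 higher, 1022 lower). It was 63.2% at a threshold of 0.01 (992 higher, 577 lower) and 62.9% without the filter on dim probes (1071 higher, 631 lower). Same-numbered arrays of this experiment shared a slide and varied together, and with the replicate block 6474 genes were called (2250 higher, 4224 lower), with the slide as a block 7314 (2488 higher, 4826 lower). The count was 2437 without Halo alone replicate 2 (1376 higher, 1061 lower) and 790 in a fit to these 6 arrays alone (619 higher, 171 lower). Which direction prevailed among the calls thus depended on the setting. Over all genes the changes within single slides correlated at r = 0.396 to 0.452.

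The third comparison asked whether both treatments move the same genes in opposite directions. Genes that rose after knockdown and fell with overexpression numbered 620, against 338 for independent lists (odds ratio 2.49, Fisher's exact test p = 5.17e-61), and 403 fell after knockdown and rose with overexpression, against 213 (odds ratio 2.40, Fisher's exact test p = 1.14e-40). Genes that rose in both numbered 375, against 279 (Fisher's exact test p = 2.52e-10), and 291 fell in both, against 258 (Fisher's exact test p = 0.0220). With the replicate block 3305 genes were called in both, 1464, 608, 582 and 651 in the same order. With quantile normalization the numbers were 267, 480, 371 and 171, so which of the opposite groups was larger depended on the normalization, while the excess of both passed in every alternative. The excess of genes that fell in both did not pass with the replicate block (Fisher's exact test p = 0.184), normexp (163 genes, p = 0.0804) or the series matrix values (248 genes, p = 0.354), nor in 3 other settings and 10 of 12 fits without single arrays (p up to 0.946). The tests are two-sided and treat genes as independent, which they are not. Both comparisons also share 1 estimate of spread per gene, which by itself can raise the number of genes called in both. Overlaps were not counted from separate fits to the arrays of each experiment, so the size of this effect is not known. Across all 18992 genes the log2 changes were uncorrelated, with Pearson's r of -0.03 and Spearman's rho of -0.04; r lay between -0.05 and 0.02 for pairs of single slides. Over the 1689 genes called in both experiments r was -0.14.

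Opposite changes were shown by ACTA2, KCNQ1OT1, SCGB1D1, FAM86B1 and LINC00640, which rose after knockdown (ACTA2 by 1.72 ± 0.06 and KCNQ1OT1 by 1.88 ± 0.22) and fell with overexpression (ACTA2 by 0.63 ± 0.06 and KCNQ1OT1 by 0.98 ± 0.22). LINC00640 was at least 1.77-fold lower with overexpression. BDH1, ZNF365, ALKAL2, SAMD13 and the growth factor gene AREG fell after knockdown (BDH1 fell by 1.82 ± 0.25, ZNF365 fell by 1.61 ± 0.25 and AREG fell by 1.24 ± 0.27) and rose with overexpression, where Halo alone left all 5 not well above background (SAMD13 at least 1.54-fold and ALKAL2 at least 1.63-fold higher). The second AREG probe read 0.48 with overexpression. With normexp the rises of BDH1, ZNF365, ALKAL2 and AREG with overexpression were not called (adjusted p = 0.161, 0.0635, 0.0683 and 0.283), nor was the fall of ALKAL2 after knockdown (adjusted p = 0.164). The bone morphogenetic protein gene BMP2, the forkhead gene FOXQ1, F8A1, AQP11 and RBM47 rose in both, F8A1 by 1.38 ± 0.11 and 1.70 ± 0.11 and FOXQ1 by 1.11 ± 0.07 and 1.30 ± 0.07. With normexp the rises of BMP2, AQP11 and RBM47 with overexpression were not called (adjusted p = 0.169, 0.449 and 0.336). SFTA3 (-0.91 ± 0.06 and -0.63 ± 0.06), PRSS57, ANO2, DNAI3 and NSMCE1-DT fell in both. FAM86B1, LINC00640, SCGB1D1, PRSS57, ANO2, DNAI3 and NSMCE1-DT each lost at least 1 of their calls when single arrays were left out, and DNAI3 with the replicate block (adjusted p = 0.0613). With normexp each of these 7 also lost at least 1 call (adjusted p from 0.0517 to 0.267). The second probe of FAM86B1 read 0.09 and 0.10. A direct test of the difference between the responses called 5766 genes, 2264 with the higher and 3502 with the lower response to overexpression, and quantile normalization moved the share of the former from 39.3% to 55.3%. The smallest adjusted p belonged to DDIT4, which fell after knockdown and rose by 0.95 ± 0.07 with overexpression (difference 4.28, adjusted p = 1.08e-08), followed by SLC6A9, ACTA2, FUT1 and CEBPB, a transcription factor gene that was 2.14-fold lower after knockdown and rose by 0.53 ± 0.05 with overexpression. SLC6A9 and FUT1 read only 0.11 and -0.04 with overexpression, so their differences came from the knockdown. The test of the difference thus also calls genes that changed in a single experiment.

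The remaining 51 of 64 list tests were not called, with camera adjusted p between 0.0728 and 0.944. Of 20 genes for the Ataxin-2 family and reported protein partners 3 rose and 3 fell after knockdown, ATXN2 included, and 1 rose and 2 fell with overexpression (adjusted p = 0.944 and 0.820). Of 34 stress granule and P-body components 7 rose and 3 fell after knockdown and 7 rose and 1 fell with overexpression (adjusted p = 0.377 and 0.162). Of 26 interferon-stimulated genes 5 rose and 10 fell after knockdown (adjusted p = 0.0728), and BST2 fell by 1.54 ± 0.09. The AU-rich mRNAs split after knockdown into 8 that rose and 7 that fell (adjusted p = 0.944), and of the ATF4 targets 4 rose and 8 fell with overexpression (adjusted p = 0.302).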

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

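The split tests and the comparisons of both responses were fixed before their results were seen, while the slide test of the ATF4 targets and the test of ATF4 targets in both directions were chosen after. The counts over only those splits that part the pairs were also added after. The test of a different response to overexpression and knockdown was applied to the gene lists called and to the genes named for both comparisons. Outlying samples were not tested for, with groups of 3.

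The direct test of the difference, overexpression response minus knockdown response, picked out 10 lists. Their mean differences less that of other genes were 1.14 for ATF4 targets, 0.80 for epithelial carcinoma line markers, 0.44 for NF-kB and inflammatory targets, 0.42 for immediate-early genes, 0.40 for AU-rich mRNAs, -0.15 for mRNA deadenylation and decay, -0.20 for translation factors, -0.24 for ribosomal proteins, -0.36 for proteasome subunits and -0.48 for oxidative phosphorylation subunits. The median of the epithelial list was lower than its mean, at 0.18. With an estimated correlation 3 of the 10 passed, the ATF4, AU-rich and immediate-early lists. The others had adjusted p of 0.126 (epithelial markers), 0.143 (proteasome), 0.164 (oxidative phosphorylation, and mRNA decay), 0.212 (NF-kB), 0.338 (translation factors) and 0.763 (ribosomal proteins).

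Among genes with all groups counted as well above background, the difference was positive for DDIT4 (4.28), FUT1 (3.46), SLC6A9 (2.67), CEBPB (1.63) and SFTA3 (0.28), and negative for KCNQ1OT1 (-2.86), ACTA2 (-2.35) and FAM86B1 (-1.30). For ALKAL2 (3.23), AREG (2.78), BDH1 (3.28), LINC00640 (-2.23), SAMD13 (2.97), SCGB1D1 (-2.98) and ZNF365 (3.86) at least 1 group was not well above background, so these fitted differences measure no size and give no order.

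The fall of ATF4 targets after knockdown was weighed first. Each slide of this experiment held as many knockdown as control siRNA arrays, so a shift common to a slide cancels in the contrast. The median of the list was -0.98 within each slide. An effect of probe GC content and signal level is argued against by a median of -0.98 after removal of these trends. That the amount of Ataxin-2 sets these mRNAs in both directions stays open, since the list was not called with overexpression (camera adjusted p = 0.302). An effect of this siRNA on other mRNAs also stays open, because only 1 siRNA treatment was measured, and so does a difference in amino acid supply between cultures. A raised level with the control siRNA stays open too, since untreated cells were not measured. Its median level of 3.29 lay above those of all other groups, but levels do not compare across the experiments.

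The rise of AU-rich and immediate-early mRNAs with Halo-Ataxin-2 was weighed second. After removal of the GC and level trends the lower of both medians was 0.33 (0.325), with quantile normalization it was 0.35, and within slides the lowest was 0.23, which argues against those trends, the scaling and the slides as the whole cause. With normexp the medians were 0.21 for AU-rich and 0.16 for immediate-early mRNAs, so their size depended on background correction. The lists share 11 of their listed members measured here, so they are not independent. A response to the transfection that differs between plasmids was not tested, and mRNA half-life and binding of Ataxin-2 were not measured.

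The fall of oxidative phosphorylation and proteasome mRNAs with Halo-Ataxin-2 was weighed last. After removal of the GC and level trends the median nearer to 0 was -0.09 (-0.0940), and with quantile normalization it was -0.09 (-0.0871), against -0.25 before. Most of the shift was thus lost with either step. Quantile normalization also changes values by signal level, so it does not tell scaling from these trends. Median scaling, which moves all genes of an array alike, kept all 13 lists called, since camera compares a list with other genes. What remained did not settle the cause. A biological explanation was not tested.

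Of the 10 splits of the 6 siRNA arrays 1, the real one, gave as many genes (5486, with 1 in the highest other) and 1 as many lists (6, with 4 in the highest other). Of the 10 splits of the plasmid arrays 1 gave as many genes (3771, with 4 in the highest other) and 2 as many lists (7, with 7 in the highest other, a split that parts all 3 pairs as the real one does). With 10 splits a share under 0.05 is out of reach. The other siRNA splits, with at most 1 gene called, still called 2 to 4 lists. The other plasmid splits, with at most 4 genes, called 1 to 7. Camera with the preset correlation thus called lists under wrong groupings too, so a list called only by it is weak evidence. These splits still mix the real groups unevenly, so they are not free of the effect. For the difference of both responses, 1 of 100 drawn splits, the real one, gave as many genes (5766, with 4245 in the highest other, the real grouping with the plasmid groups exchanged). Many draws do not part the pairs. Of the 43 that part all 3 plasmid pairs, as the real one does, 1 gave as many, and of the 21 that part the siRNA pairs as well also 1. The share stayed under 0.05 but near it in the last. These splits exchange labels in both experiments, so they stand for no effect in either and not for equal responses. An effect in a single experiment would also place the real grouping high, so the shares do not decide whether the responses differ.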

How the results depend on the processing

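The fits without the arrays of a slide, the removal of GC and level trends, and for gene lists the slide block and the median scaling were chosen after seeing the data. Of the values of single genes, lists and direction groups under alternatives, 1350 kept direction and side of the threshold, 98 fell short of it, 2 newly passed and 16 counts moved by over 1.5 times, and without single arrays 1621, 81, 0 and 12. The cause was not tested unless it is stated. Genes called with overexpression numbered 2376 with normexp, 1702 without the filter on dim probes, 790 from the 6 arrays alone, 6474 with the replicate block, 7314 with the slide as a block, 1569 at a threshold of 0.01 and 1300 without slide 1. Genes called with knockdown numbered 3417 at 0.01 and 3392 without slide 1. Same-numbered arrays of the knockdown correlated at 0.42, 0.09 and 0.14 and shared a slide, but were not taken as paired since not all were over 0.1, knockdown replicate 3 correlated better with another number, and the replicate block gave 7329 calls there. With overexpression the block ended the calls of OXGR1, DNAI3 and NECTIN3-AS1 and of no other named gene or list. For the difference of both responses the counts were 3746 without the filter, 3341 at 0.01 and 3512 without slide 1. The overlap numbered 1082 with normexp, 614 without the filter, 3305 with the replicate block and 3921 with the slide as a block. Lists called numbered 11 after removal of GC and level trends and 12 with quantile normalization, each with 8 of the 13 of the main fit, 22 without the filter, 3 with an estimated correlation and 43 with fry, which tests another question. Leaving out single arrays gave 4114 to 5748 calls for knockdown, 2437 (without Halo alone replicate 2) to 3783 for overexpression, 4625 to 5803 for the difference, an overlap of 1093 (without control siRNA replicate 2; 1103 without Halo alone replicate 2) to 1742, 13 to 14 lists and a correlation of -0.04 to -0.01 (-0.0388 to -0.00874).

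The sign reversed for ATXN2L on knockdown with quantile normalization (-0.0763), for ATXN2L on overexpression with quantile normalization (0.14) and without Halo-Ataxin-2 replicate 1 (0.0537) or Halo alone replicate 3 (0.03; lowest without a single array -0.178), for cytoplasmic ribosomal proteins on overexpression after removal of GC and level trends (0.00, 0.00378), and with the next brightest probe for FAM86B1 on overexpression (0.10), AGO1 on overexpression (-0.10) and TFEB on overexpression (-0.19). Tests of the next brightest probe used unadjusted p. The test of UAUUUAU in the 3 prime UTR and its alternatives were not run, for want of a genome. The share of spots well above background, 47.8% to 56.0%, limits what can be said of dim genes, and the number of arrays limits the precision of all values.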

Other observations

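The tests of intronless genes, of GC content and of CAG triplets were fixed before their own results were seen but prompted by rises already seen, and the test of DNA carry-over and the comparison with histone genes were chosen after. A list of genes without introns tended to rise with Halo-Ataxin-2. It was written from textbook knowledge after single intronless genes had been seen among the rises, and leaves those out. Of 63 measured genes 32 rose and none fell, the median was 0.44 against -0.10 for all genes, and within slides it was 0.40, 0.41 and 0.53. After knockdown 11 rose and 5 fell, with a median of 0.03 (camera p = 0.693 with an estimated correlation).

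The set tested higher than other genes with overexpression (camera p = 0.000180 with an estimated correlation). The median stayed at 0.44 (0.443) after removal of GC and level trends, with limma camera p = 0.000701 (estimated correlation). Names without a recognised gene had a median of -0.18 (-0.175), below that of all genes. Whether these names lie outside known genes was not checked, so this does not decide on carry-over of genomic DNA as the cause. Replication-dependent histone genes, which lack introns too and are not in the list, did not share the rise, with 2 of 40 higher, 1 lower and a median of 0.03 (camera adjusted p = 0.206, and 0.733 with an estimated correlation). The pattern is thus one of the genes in the list, and whether the lack of introns matters stays open. The half-life of these mRNAs and binding of Ataxin-2 were not measured.

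The mRNA of the construct may bind probes that carry CAG triplets, since ATXN2 has a CAG repeat in its coding part. The rises of SOX13, AGO1 and TFEB had been seen when this test was set, the probe sequences had not. Of 7 kept probes with at least 4 CAG triplets in a row 4 rose, those of SOX13, AGO1, TFEB and CDK13, the last named after its value was seen. Of 5 probes with such CTG runs 4 fell, among them the probes of PIEZO1 (-0.62 and -0.52), which stand for the same gene. The medians were 1.83 and -0.86, a difference of 2.69 (exact permutation test, one-sided, p = 0.0126). The fall of the CTG probes adds to this difference, and its cause was not tested. The test was not made on independent probes, because the probes of SOX13, AGO1 and TFEB that prompted it are among the 7. Of the rest of the 7, the CDK13 probe read 2.16 and the others -0.02, -0.05 and -0.15, so the p-value rests largely on the prompting probes. The rises of these probes are thus a candidate for cross-hybridisation, and by themselves do not show a rise of these genes.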
